A study of Mus musculus with 15 samples.

How the data were processed

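Libraries from 15 samples of mouse podocyte RNA were made with an mRNA-Seq kit, per the labels' protocols, and 3 tables of the whole series were used: ApoM-treated against vehicle knockout cells, CYM50358-treated against vehicle knockout cells, and knockout against wild-type cells. Per the submitters' processing notes the tools were FastQC, Trim Galore, STAR and edgeR and the genome build mm39; their roles, settings and versions are not given in the sources used here, nor is whether counting used strand, so overlapping and antisense genes and near-identical copies are uncertain. Each table gives 57132 genes with identifier, name and location per the file headers.

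The columns per library hold signal that the authors deposited, without a stated unit; the values sum to 972556 to 1026940 per library and behave as CPM with a further scaling factor. Per the file headers, the authors also deposited a mean signal over libraries, log2 fold changes with standard errors on the log2 scale, a test statistic (a score) and p-values with adjusted p-values. Those column names are the ones DESeq2 writes, while the submitters' processing notes name edgeR. DESeq2 run here on recovered reads, over the 9 treatment libraries or the 6 genotype libraries, gave the same counts of genes at an adjusted p under 0.05 as the authors' deposited table (6, 958 and 6367), with the largest difference in log2 fold change 5.47e-05 over 16276 genes with a mean above 10. The DESeq2 alternative counted elsewhere (6452 genes between the genotypes, 18 for ApoM, 716 for CYM50358 and 595 in the direct comparison) is another fit, on the libraries of the 2 groups compared only and with DESeq2's filter on low means set for an adjusted p of 0.05.

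In each library the values were whole multiples of a smallest step, and dividing by it gave whole reads for 100% of values above 0 (tolerance 0.01). On these reads edgeR called 6517 genes between the genotypes, 3 for ApoM, 165 for CYM50358 and 214 in the direct comparison. Of the genes, 26706 were at 0 in all libraries. Recovered totals were 45417221 to 83166742 reads, so 1 read is worth a signal of 0.0118 to 0.0221. The 3 vehicle knockout columns were identical in both treatment tables and were used once. No library was a copy of another: replicates of each group differed beyond sampling noise, with chi-square values per degree of freedom of at least 9.83. The highest were those of wild-type replicate 1 against replicates 2 (47.7) and 3 (50.0), which stood at 9.83 from each other.

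The design fixed before the data were examined named edgeR for counts and limma for normalized values. As the columns are signal, the main test was limma with a trend on log2(signal + 1), on the libraries of the 2 groups compared, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05 without a fold minimum. Fold changes are on the log2(signal + 1) scale, which understates changes of low genes. Genes with a signal of at least 0.5 in at least 3 libraries of a fit were tested; this minimum was set before the tables of results were read. The comparisons were knockout minus wild type, ApoM minus vehicle, CYM50358 minus vehicle and ApoM minus CYM50358, the last possible because the 9 treatment libraries share a scale.

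Gene lists, 29 in number, were fixed before the data were examined and tested with camera at a correlation of 0.01, with adjustment over the lists of a comparison. Alternatives were camera with the correlation estimated per list, and fry, whose p tests whether the genes of a list move, on balance, one way and whose mixed p whether they change in either direction; fry compares a list with no other genes. For each list, calls over all genes tested stand beside those adjusted over the list alone.

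Genes were named by a rule also fixed in advance: Col4a3, Col4a4, Col4a5, S1pr1 to S1pr5 and Apom in every comparison; in each main comparison the 10 largest rises and falls among called genes with an average above the median of tested genes, no overlap between groups and a named symbol (where fewer than 5 pass in a direction, also the 5 with the smallest p, as not past the threshold); up to 4 members with the smallest p for each list that passes or has at least 3 called members; the 5 largest rises and falls in the direct comparison; and up to 5 genes called in both treatments in the same direction. Some genes that this rule takes are not reported here.

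Replicate numbers come from the sample titles. Same-numbered wild-type and knockout libraries had correlations of 0.371, 0.217 and 0.105 between their deviations from the group means (above 0.1 in each case), and same-numbered ApoM and CYM50358 libraries 0.132, 0.115 and 0.132, so the numbers were taken to pair the samples there. Wild-type replicate 3 correlated better with knockout replicate 2 (0.197) than with knockout replicate 3 (0.105), so the pairing between the genotypes is an assumption. Unchanged groups against shared vehicle libraries were simulated by random mixing of the residuals of the libraries, 100 times, as independent libraries without the pairing.

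Alternatives planned were pseudocounts of 0.5 and 0.1, no filter, a mean of at least 1, the replicate block, leaving out each library, a minimum of 2-fold and the authors' adjusted p. Added after the data were seen were edgeR's quasi-likelihood test, DESeq2 and limma-voom on the recovered reads, with other scaling factors and filters, all libraries in 1 fit, reads thinned to equal totals, camera with the replicate block, subtraction of the median of each chromosome, and levels of the other vehicle knockout set against wild type. The main test was first run on simulated reads with 200 changed genes in each comparison. Of 50 genes changed at each of 1.5-fold, 2-fold, 4-fold and 8-fold it recovered 70%, 94%, 98% and 100% for knockout against wild type (14221 genes tested). For ApoM against vehicle it recovered 82%, 92%, 98% and 98% (13808 genes), for CYM50358 78%, 86%, 100% and 100% (13833 genes) and for the direct comparison 72%, 88%, 98% and 100% (13837 genes). With 200 changed genes the adjustment is easier to pass than with few. These shares can therefore overstate recovery where few genes are called, as for ApoM. Genes left unchanged made up 16 of 197 calls between the genotypes, 15 of 200 for ApoM, 16 of 198 for CYM50358 and 6 of 185 in the direct comparison. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. The reference annotation at hand is of another build, so locations are those of the files, and only GC content and length of transcripts, matched by gene identifier, were taken from it.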

Results

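RNA was sequenced from mouse podocytes, the epithelial cells that cover the filtering capillaries of the kidney and make part of their basement membrane. Col4a3 encodes a chain of collagen IV, and mice without it are a model of Alport syndrome, an inherited kidney disease. The 15 libraries formed 5 groups of 3: wild-type cells with vehicle, knockout cells with vehicle in 2 separate sets, knockout cells given apolipoprotein M (ApoM, a plasma carrier of the lipid mediator sphingosine-1-phosphate), and knockout cells given CYM50358, an antagonist of the sphingosine-1-phosphate receptor S1PR4, each for 24 h. One vehicle knockout set stood beside the wild-type cells and the other beside the treated cells. The 2 sets are different libraries, and the tables that hold them were normalized separately, so tests were made only within a table. Library depth was 46348481 to 52070194 reads in wild-type cells, 45417221 to 54290968 in the knockout cells beside them, 57735687 to 62201989 in the vehicle knockout cells of the treatment table, 60919831 to 77779920 after ApoM and 60455130 to 83166742 after CYM50358. Expression is given as signal, a scaled CPM, as mean ± SD, and fold changes as log2 of signal plus 1. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

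The comparison of knockout with wild-type podocytes asks how the lines differ without treatment. Col4a3 itself (ENSMUSG00000079465.9, chromosome 1, 82564642 to 82699780, mm39) fell from 1085 ± 168 in wild-type to 68.3 ± 11.7 in knockout cells (n = 3 each; log2 fold change -3.97, SE 0.13, adjusted p = 5.8e-08). Reads remained in every knockout library, and the labels do not say which part of the gene is deleted, so reads outside that part check nothing. Its partner chain Col4a4 fell (603.8 ± 45.9 to 448.8 ± 40.9, log2 fold change -0.43), while Col4a5, another chain of the same network, rose (948.5 ± 61.9 to 1170 ± 44.1, log2 fold change 0.30), a call lost without wild-type replicate 3 (Col4a5 adjusted p = 0.052).

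Matrix genes were among the largest changes in both directions. Bgn, which encodes the matrix proteoglycan biglycan, fell from 986.5 ± 59.8 to 6.54 ± 1.32 (log2 fold change -7.05, SE 0.12), and falls were also large for the proprotein convertase Pcsk5 (-5.68), the heparan sulfate sulfatase Sulf1 (-4.60), Sdk1 (-3.42), the GABA transaminase Abat (-3.31), Igfbp5 (-3.18), the fibrillar collagen gene Col5a2 (-3.15), the amino acid transporter Slc38a1 (-3.10) and the potassium channel Kcnk1 (-2.99). Loxl2, a collagen cross-linking enzyme, rose from 18.6 ± 3.12 to 527.2 ± 9.47 (log2 fold change 4.77, SE 0.10). It was joined by Sfrp2 (4.73), AI506816 (4.57), the collagen genes Col3a1 (4.24) and Col1a1 (4.22), Galnt18 (2.99), Parvb (2.80), the Wnt agonist Rspo2 (2.64), Ogn (2.63) and Armc10 (2.59). Col1a1 was 24.3 ± 4.1 in wild-type cells and 472.9 ± 95.3 in the knockout cells tested. It was 48.6 ± 10.8 in the other vehicle knockout set, whose table was normalized separately. Levels of that set minus wild type were compared without a test, after the values were seen. Their log2 differences had the same sign for the 123 genes named by rule and called here. The same wild-type libraries enter both differences, so part of that agreement is built in. The differences were smaller by over 1 for 5 of these genes: Col1a1 (0.96), Rspo2 (1.04), Slc38a1 (-2.00), Lama1 (-0.22 against -1.53) and Ucp2 (-0.62 against -2.15). Same-sign changes under 1 cannot be counted that way. Among them Rpsa (-0.004 against -0.70) and Ifit3 (0.09 against 0.75) nearly lost their difference, while that of S1pr2 grew (1.19 against 0.54). In all, 3239 genes rose and 3156 fell of 14313 tested with limma, and 345 rose and 526 fell by at least 2-fold. The groups did not overlap for 55.8% of tested genes, against 10% by chance, and the authors' deposited table has 6367 genes at an adjusted p under 0.05, of which 5816 were also called here, all in the same direction.

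**Figure D1:**
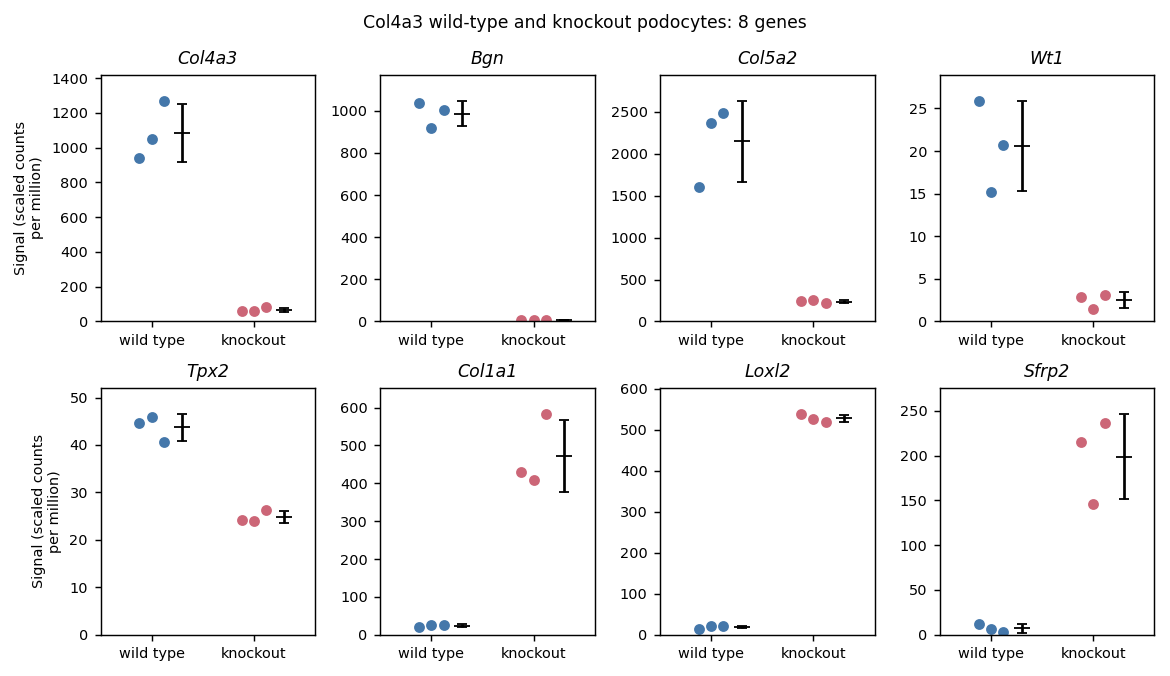
Signal (scaled CPM, linear axes from 0) of 8 genes in the 3 wild-type and 3 knockout libraries with vehicle; points are libraries, and the dash and bar are the mean and SD. Col4a3, Bgn, Col5a2, Wt1 and Tpx2 were lower and Col1a1, Loxl2 and Sfrp2 higher in knockout cells, with no overlap between the groups.

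Genes of cell division were lower in knockout cells. Of 30 genes of the G2 and M phases, 26 fell and none rose, among them Tpx2 (43.7 ± 2.78 to 24.8 ± 1.34, log2 fold change -0.79), Cenpe (-0.96) and Ccnb1 (-0.98), and 27 fell when adjusted over the list alone. Of 30 S phase genes, 20 fell and 1 rose, including the cyclin genes Ccne1 (-0.72) and Ccne2 (-1.11), with 20 and 1 when adjusted over the list alone. Camera gave an adjusted p of 3.2e-07 for the G2 and M list and 0.00033 for the S list, and for each list the adjusted p = 0.91 with an estimated correlation. The 2 vehicle knockout sets also differed in such genes, in levels from tables normalized separately and without a test. The other set minus wild type gave -1.5 for Tpx2, -1.7 for Cenpe, -2.1 for Ccnb1, -1.6 for Ccne1 and -1.8 for Ccne2. Mki67, a marker of dividing cells, was 55.6 ± 16.1 in wild-type cells, 28.0 ± 2.19 in the knockout cells tested and 4.47 ± 2.14 in the other set. Of 26 genes of cholesterol synthesis and uptake, 12 rose and none fell (12 and 1 adjusted over the list alone), among them Hsd17b7 (0.61), Insig1 (0.85), Lss (0.55) and Cyp51 (0.78); camera's adjusted p was 0.028, and the adjusted p = 0.91 with an estimated correlation. That call was lost without wild-type replicate 1 (adjusted p = 0.11) and without knockout replicate 2 (0.10). These were the 3 of 29 lists past the threshold. With replicate number as a block, a further list passed, the genes encoded by mitochondrial DNA (adjusted p = 0.021 against 0.23 without the block), as it did without wild-type replicate 3 (0.031). Without the block that list had adjusted p = 0.91 with an estimated correlation. Reads from mitochondrial DNA made up 0.882% to 1.68% of wild-type and 1.30% to 2.02% of knockout libraries.

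Podocyte markers moved both ways. Of 25 measured, 6 rose and 12 fell (7 and 12 adjusted over the list alone), with falls of Wt1, a transcription factor of podocytes (20.6 ± 5.30 to 2.49 ± 0.92, log2 fold change -2.64), and of Pla2r1 (-1.98), and rises of the transcription factor Lmx1b (2.33) and of Thsd7a (1.31). The list as a set did not pass (camera adjusted p = 0.33). Fibrillar matrix genes split into 10 that rose and 10 that fell of 28, and basement membrane genes into 4 and 10 of 24, with the same counts adjusted over the list alone, and the laminin gene Lama1 fell (-1.53). Among genes of inflammation, 9 of 23 fell and 4 rose (10 and 4 adjusted over the list alone), with falls of Icam1 (-1.93), the complement gene C3 (-2.14) and Lcn2 (-2.44) and a rise of Tnfaip3 (1.09), which lies on chromosome 10. Fatty acid genes also went both ways: 10 of 30 of synthesis and lipid droplets rose and 8 fell, the same adjusted over the list alone, and 7 of 30 of oxidation rose and 6 fell (8 and 6 adjusted over the list alone), with Cpt1a at 0.84, Acaa1a at -0.97 and the uncoupling protein gene Ucp2 at -2.15. Over all tested genes 44.7% were called, so many calls in a list are not particular to it. Camera passed neither the matrix lists (adjusted p = 0.76 for fibrillar matrix and 0.4 for basement membrane) nor the inflammation list (0.23). It passed neither fatty acid list (0.76 each).

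Markers of other cell types also differed. Of 5 measured endothelial markers 3 fell, including Erg (8.74 ± 1.42 to 1.09 ± 0.31, log2 fold change -2.22), and none rose. Another of the 3, Ehd3 (-0.26, limma adjusted p = 0.024), lost its call without knockout replicate 2 (0.089) or 3 (0.057). It also did without wild-type replicate 2 (0.079) or 3 (0.084). Of 10 epithelial markers of the parietal layer and tubule, 5 fell and 1 rose, with Cldn2 at -2.90, Spp1 at -2.38, Pax2 at -0.57 and Cdh16 at 1.49. Of 13 markers of mesangial cells and fibroblasts, 5 rose and 3 fell, with Col1a1 at 4.22, Serpine2 at 0.92, Pdgfrb at -1.12 and Cspg4 at -2.91, and of 2 leukocyte markers 1 fell. All these counts were the same adjusted over the list alone, and 44.7% of all tested genes were called. Camera passed none of these lists over all libraries, with adjusted p-values of 0.11 for endothelial, 0.23 for parietal and tubular, 0.56 for mesangial and fibroblast and 0.47 for leukocyte markers, and the endothelial list passed without wild-type replicate 1 (0.045). Fry, which asks only whether the genes of a list move, on balance, one way, passed the endothelial list (adjusted p = 0.039, and 0.12 with replicate number as a block) and the parietal and tubular list (0.039, and 0.0045 with the block), both lower in knockout cells, and neither the mesangial and fibroblast list (0.064) nor the leukocyte list (0.13).

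Genes of sphingosine-1-phosphate handling changed in both directions. Of 12 measured, 4 rose and 3 fell (5 and 3 adjusted over the list alone), including the phosphatase genes Plpp1 (0.82) and Plpp2 (0.54), the lyase gene Sgpl1 (0.42) and the kinase gene Sphk2 (-0.51). The receptor gene S1pr2 rose (17.0 ± 3.83 to 24.9 ± 2.33, log2 fold change 0.54, adjusted p = 0.014, and 0.058 without knockout replicate 2), S1pr3 did not pass (9.29 ± 3.10 against 12.4 ± 1.81, adjusted p = 0.11, 0.024 with replicate number as a block and 0.0021 without wild-type replicate 1), nor did S1pr1 (0.44 ± 0.24 against 0.60 ± 0.16, adjusted p = 0.41). In sphingolipid metabolism 5 of 31 genes rose and 10 fell, the same adjusted over the list alone, with Smpdl3a at -2.02, Smpd3 at 1.87, the desaturase gene Degs1 at -0.51 and the ceramide synthase gene Cers2 at -0.31. Camera passed neither list (adjusted p = 0.57 for sphingosine-1-phosphate handling and 0.73 for sphingolipid metabolism). The share of all tested genes called was 44.7%.

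The direction of the difference depended on the chromosome. The median log2 fold change was 0.28 over the 803 tested genes of chromosome 8 and 0.28 over the 693 of chromosome 10, where 455 and 394 genes rose and 52 and 53 fell. Medians were also above 0 on chromosomes 5 (0.17), 15 (0.17) and 19 (0.17), and lowest on chromosomes 4 (-0.16) and 6 (-0.17). Of the genes named above, Plpp2, Sgpl1, Lss, Smpdl3a and Tnfaip3 lie on chromosome 10 and Kcnk1, Smpd3 and Cdh16 on chromosome 8. AI506816, Armc10, Insig1, Cyp51, Sdk1 and Spp1 lie on chromosome 5, Parvb, Rspo2 and Slc38a1 on 15, and Cpt1a, Pcsk5 and Pax2 on 19. Of these, Sdk1, Spp1, Slc38a1, Pcsk5 and Pax2 fell and the others rose. The split by chromosome was chosen after the values were seen. With the median of each chromosome subtracted, 5305 genes were called, of which 4666 were among the 6395.

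**Figure D2:**
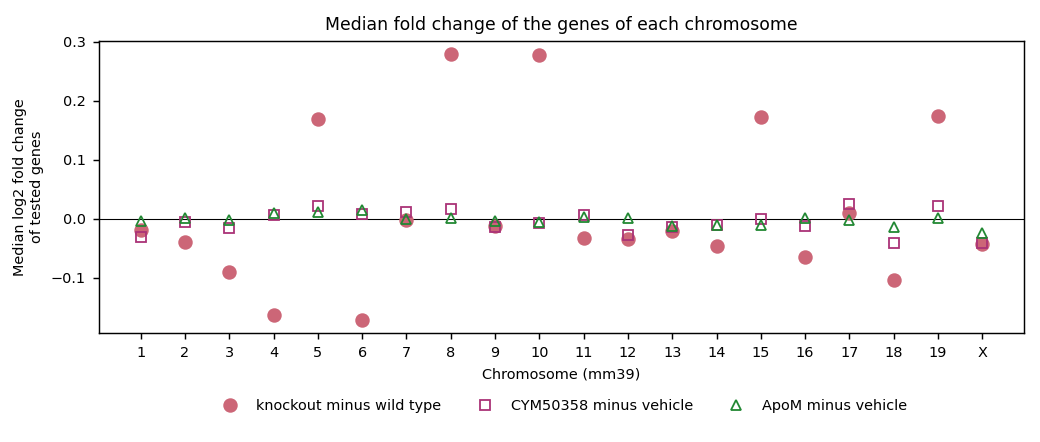
Median log2 fold change of the tested genes of each chromosome, for knockout minus wild-type cells (filled circles), CYM50358 minus vehicle (squares) and ApoM minus vehicle (triangles). Knockout minus wild type stood at 0.28 on chromosomes 8 and 10 and at -0.17 on chromosome 6, while the treatment medians stayed between -0.04 and 0.02.

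Before the treatments, the levels of their targets were read. S1pr4, the receptor that CYM50358 blocks, had 0 reads in each of the 3 vehicle knockout libraries of the treatment table, which allows a signal of up to 0.048 to 0.052 per library. It had 7, 16 and 0 reads in the ApoM libraries, 0, 1 and 21 in the CYM50358 libraries, 9, 1 and 5 in wild-type cells and 1, 3 and 0 in the knockout cells beside them. S1pr5 and Apom were as low, with at most 15 and 11 reads in any library, and these 3 genes were too low to be tested. S1pr2 was the most expressed receptor gene in vehicle knockout cells (39.4 ± 1.94), followed by S1pr3 (15.0 ± 2.51) and S1pr1 (1.05 ± 0.45). Such limits cover counting error only.

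The ApoM comparison asks what an added carrier of sphingosine-1-phosphate changes in knockout cells. Of 13839 genes tested with limma, 2 rose and 4 fell. Spp1, which encodes osteopontin, fell from 278.8 ± 54.7 to 166.7 ± 18.8 (n = 3 each; log2 fold change -0.73, SE 0.10, adjusted p = 0.0055). Falls were also found for the fatty acid desaturase gene Scd1 (122.9 ± 9.07 to 86.8 ± 6.92, log2 fold change -0.50, adjusted p = 0.0055), for Cp, the gene of the copper carrier ceruloplasmin (98.1 ± 6.52 to 69.6 ± 5.84, -0.49, adjusted p = 0.0061), and for the matrix gene Efemp1 (147.5 ± 4.72 to 116.4 ± 4.64, -0.34, adjusted p = 0.024). The transcription factor gene Atf5 rose from 106.3 ± 4.34 to 143.7 ± 13 (0.43, adjusted p = 0.013) and the metallothionein gene Mt1 from 32.7 ± 2.14 to 45.6 ± 2.55 (0.47, adjusted p = 0.024). Not past the threshold, the smallest p-values for higher values included those of Anxa8 (0.31), Slc7a5 (0.38), Aldh1l2 (0.58), Hmox1 (0.25) and Chac1 (0.48), and for lower values those of Cdh13 (-0.47), Cyp51 (-0.37), Cxcl10 (-0.50) and Adamts14 (-0.59), with adjusted p-values of 0.14 to 0.37.

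Each of these calls was lost when at least 1 of the libraries was left out, which also lowers the number of libraries tested. Without ApoM replicate 2 no gene was called by limma, with adjusted p-values of 0.15 for Spp1, Scd1 and Cp, 0.35 for Atf5 and 0.44 for Efemp1 and Mt1. Without ApoM replicate 3 only Scd1 was, with Spp1 and Cp at 0.058, Atf5 at 0.17, Efemp1 at 0.21 and Mt1 at 0.22. Efemp1 and Mt1 were also lost without ApoM replicate 1 (0.055 and 0.054) and without vehicle replicate 2 (0.12 each). Without vehicle replicate 1 there were 12, which included Fdps (0.01), Cyp51 (0.02), Cdh13 (0.02) and Aldh1l2 (0.041). On the recovered reads edgeR called 3, all of them falls (Spp1, Scd1 and Cp), and DESeq2 18, and limma with all libraries in 1 fit called 0. At an unadjusted p under 0.05 there were 755 of 13839 genes with all libraries, where a share of 0.05 of unchanged genes would pass by chance. The groups did not overlap for 10.7% of genes against 10% by chance. The authors' deposited table has 6 genes at an adjusted p under 0.05, 5 of them among the 6 called here.

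As a set, the genes of cholesterol synthesis and uptake were lower after ApoM (median log2 fold change -0.25; camera adjusted p = 1.1e-21), and the adjusted p = 0.33 with an estimated correlation. None of the 26 passed singly with limma over all genes tested, 17 fell when adjusted over the list alone, 19 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 1. Examples are Cyp51 (85.4 ± 8.11 in vehicle, 65.8 ± 7.29 after ApoM), Idi1 (23.8 ± 3.55 and 16.3 ± 3.41), Fdps (83.6 ± 15.3 and 63.0 ± 7.41) and Lss (44.0 ± 3.52 and 35.1 ± 3.31). The genes of the unfolded protein and integrated stress response stood higher (median 0.08, camera adjusted p = 3.1e-06), with the adjusted p = 0.41 with an estimated correlation; no member passed over all genes tested with limma or edgeR and 2 did with DESeq2, 14 had an unadjusted p under 0.05, and 12 rose and 1 fell adjusted over the list alone. Slc7a5, Chac1, Ppp1r15a (0.31) and Ddit3 (0.34) had its smallest p-values. NRF2 targets, genes of the response to oxidants, also stood higher (median 0.09, camera adjusted p = 3.1e-06), and the adjusted p = 0.33 with an estimated correlation. Actin and focal adhesion genes stood lower (median -0.06, camera adjusted p = 2.8e-05), and the adjusted p = 0.44 with an estimated correlation. Camera passed 13 of the 29 lists, and no list passed with an estimated correlation. The 4 lists named here passed without each library in turn. Spp1 belongs to the list of parietal and tubular epithelial markers, which also stood lower (camera adjusted p = 0.0041, and adjusted p = 0.33 with an estimated correlation). Beside these shifts, 10 of 11 genes encoded by mitochondrial DNA stood higher (camera adjusted p = 0.0084, and adjusted p = 0.47 with an estimated correlation), a call lost without vehicle replicate 2 (0.34) or ApoM replicate 1 (0.075). Reads from mitochondrial DNA made up 3.17% to 3.20% of each ApoM library and 2.60% to 3.18% of each vehicle library.

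The CYM50358 comparison asks what the S1PR4 antagonist changes in the same knockout cells. Angptl4, an inhibitor of lipoprotein lipase, fell from 53.4 ± 4.19 to 9.78 ± 0.70 (n = 3 each; log2 fold change -2.34, SE 0.10, adjusted p = 6.2e-11). Its level was 14.4 ± 1.52 in the other vehicle knockout set, in a table normalized separately. Pdk4, a kinase that restrains glucose oxidation, fell from 104.5 ± 22.4 to 51.0 ± 8.32 (-1.01), and Cpt1a, which brings fatty acids into mitochondria, from 287.6 ± 9.97 to 196.3 ± 4.46 (-0.55, SE 0.06). In that other set Pdk4 was 39.0 ± 3.19 and Cpt1a 186.1 ± 17.9, also below the vehicle cells tested here. The desaturase gene Scd1 rose from 122.9 ± 9.07 to 275.1 ± 51.9 (1.14, SE 0.10, adjusted p = 3.2e-06), Scd2 from 973.1 ± 70.6 to 1752 ± 205 (0.84) and Fdps, an enzyme of cholesterol synthesis, from 83.6 ± 15.3 to 149.0 ± 5.40 (0.84). For these rises the other set did not stand near the treated level, with Scd1 at 102.2 ± 2.58 and Fdps at 52.5 ± 9.40. Mt1 rose most among the genes named by rule (32.7 ± 2.14 to 75.0 ± 8.93, 1.17), and the others were Bri3 (0.93), Uap1l1 (0.88), the interferon-induced gene Ifit3 (0.73), the galectin gene Lgals3 (0.72), Pdzk1ip1 (0.68) and Insig1 (0.68). Further falls were those of the chemokine gene Cxcl10 (-0.68), Kank3 (-0.57), Klf11 (-0.56), the serine synthesis gene Psat1 (-0.55), the activin gene Inhba (-0.54), Tubb3 (-0.54) and Hipk2 (-0.53). Of the genes named here only Hipk2 lost its call when a library was left out: vehicle replicate 1 (adjusted p = 0.10) or 2 (0.065), or CYM50358 replicate 2 (0.07) or 3 (0.069).

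In all, 186 genes rose and 173 fell of 13877 tested, 4 and 5 of them by at least 2-fold, and the groups did not overlap for 20.9% of genes against 10% by chance. The count was 184 without vehicle replicate 1, 173 without vehicle replicate 2, 81 without CYM50358 replicate 2 and 168 without CYM50358 replicate 3, and on the recovered reads edgeR called 165 and DESeq2 716. The authors' deposited table has 958 genes at an adjusted p under 0.05, of which 353 were among the 359 called here.

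**Figure D3:**
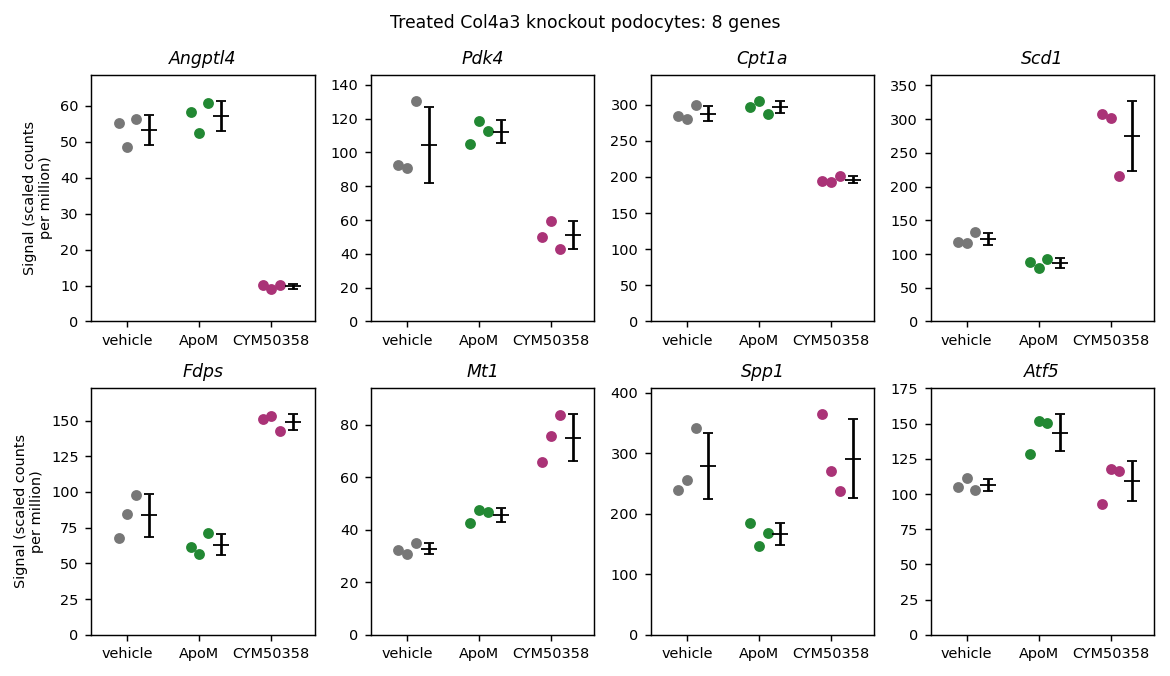
Signal (scaled CPM, linear axes from 0) of 8 genes in knockout cells with vehicle, ApoM or CYM50358, 3 libraries each; points are libraries, and the dash and bar are the mean and SD. Angptl4, Pdk4 and Cpt1a were lower and Scd1, Fdps and Mt1 higher after CYM50358, and Spp1 and Scd1 were lower after ApoM.

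By list, 16 of 26 cholesterol genes rose and none fell (21 and 0 adjusted over the list alone), including Hmgcs1 (0.52), Tm7sf2 (0.94) and Lss (0.59); camera's adjusted p was 5.6e-25, and the adjusted p = 0.18 with an estimated correlation. Genes of the lysosome and autophagy rose in 17 of 35 cases and fell in none (22 and 0 adjusted over the list alone), among them the hydrolase genes Hexa (96.8 ± 5.58 to 130.1 ± 4.32, 0.42) and Ctsa (0.38) and the proton pump gene Atp6v0d1 (0.36), with a camera adjusted p of 1.7e-20 and adjusted p = 0.08 with an estimated correlation. Of 30 genes of fatty acid synthesis and lipid droplets, 7 rose and none fell (13 and 1 adjusted over the list alone), including Fads1 (0.33) and Acsl3 (0.54), with camera adjusted p = 3.4e-08 and adjusted p = 0.08 with an estimated correlation. Of 30 fatty acid oxidation genes, 7 fell and none rose (8 and 0 adjusted over the list alone), among them Cpt1a, Pdk4 and Ucp2 (-0.43), with camera adjusted p = 0.00024 and adjusted p = 0.30 with an estimated correlation. Of 18 genes of cholesterol efflux and other LXR targets, 4 rose and none fell (7 and 0 adjusted over the list alone): Srebf1 (0.45), Npc2 (0.34), Mylip (0.42) and Lpcat3 (0.25), with camera adjusted p = 4.9e-06 and adjusted p = 0.18 with an estimated correlation. These 5 lists passed without each library in turn. Single calls were lost without CYM50358 replicate 2 for Npc2 (0.054), Mylip (0.076), Fads1 (0.077), Acsl3 (0.097) and Lpcat3 (0.16), and without vehicle replicate 2 for Mylip (0.06) and Lpcat3 (0.16). Lpcat3 was lost without vehicle replicate 3 (0.15) and CYM50358 replicates 1 (0.055) and 3 (0.15) as well.

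NRF2 targets rose in 5 of 26 cases and fell in none (10 and 1 adjusted over the list alone), with Hmox1 at 0.52, the ferritin genes Fth1 at 0.42 and Ftl1 at 0.45 and Gpx4 at 0.35; camera's adjusted p was 9.9e-09, and the adjusted p = 0.13 with an estimated correlation. Basement membrane genes fell in 5 of 25 cases and rose in none (7 and 0 adjusted over the list alone), among them Nid1 (-0.37), Lama1 (-0.87), Itgb1 (-0.31) and Col4a5 (1106 ± 134 to 849.1 ± 68.0, -0.38, adjusted p = 0.022); camera's adjusted p was 6.6e-06, and the adjusted p = 0.24 with an estimated correlation. Actin and focal adhesion genes fell in 5 of 36 cases and rose in none (13 and 1 adjusted over the list alone), including Itgav (-0.36), Myl9 (-0.35), Flna (-0.37) and Tpm4 (-0.30), with camera adjusted p = 6.4e-06 and adjusted p = 0.35 with an estimated correlation. These 3 lists passed without each library in turn.

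In the stress response list 4 of 32 genes fell, Psat1, Pdia6 (-0.28) and Hsp90b1 (-0.30) among them, and 1 rose, Ddit3 (0.56), with 10 and 2 adjusted over the list alone. Camera's adjusted p was 0.0082, and the adjusted p = 0.59 with an estimated correlation; the call was lost without vehicle replicate 2 (0.22) and without CYM50358 replicate 1 (0.077). Interferon response genes rose in 3 of 26 cases, the same adjusted over the list alone: Ifit3, Ifit3b (0.64) and Ifit2 (0.30). Camera's adjusted p was 0.028, and the adjusted p = 0.24 with an estimated correlation; the call was lost without vehicle replicate 3 (0.077) and without CYM50358 replicate 3 (0.095). Of 23 podocyte markers, 2 fell, Nes (-0.45) and Thsd7a (-0.32), and 1 rose, Clic5 (0.63), with 4 and 1 adjusted over the list alone. Of the markers of other cell types, 1 of 11 parietal and tubular ones rose and 1 fell, and none of 4 endothelial, 9 mesangial and fibroblast and 4 leukocyte markers passed with limma, edgeR or DESeq2, with 0, 1 and 0 at an unadjusted p under 0.05. The leukocyte list passed without vehicle replicate 1 (0.031) and without CYM50358 replicate 1 (0.041), against 0.21 with all libraries.

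Many calls of single genes in the oxidant, matrix, actin, stress, interferon and podocyte lists were lost when a library was left out. Leaving out a library also lowers the number tested, so such a loss does not show that 1 library carried the change. Without CYM50358 replicate 2, those of Hmox1, Psat1, Ifit3 and Nes stayed, and the call was lost for Itgav (0.056), Fth1 (0.064), Ftl1 (0.064), Ddit3 (0.073), Nid1 (0.076), Lama1 (0.077), Thsd7a (0.094), Ifit3b (0.098), Pdia6 (0.10), Gpx4 (0.11), Col4a5 (0.13), Myl9 (0.13), Flna (0.14), Hsp90b1 (0.16), Ifit2 (0.16), Tpm4 (0.20), Clic5 (0.23) and Itgb1 (0.25). The adjusted p was 0.056 for Nid1 to 0.16 for Itgb1, Ifit2 and Clic5 without vehicle replicate 2, where Col4a5, Flna, Gpx4, Hsp90b1, Lama1, Myl9, Pdia6, Thsd7a and Tpm4 were lost too. It was 0.069 for Lama1 and Ifit3b to 0.18 for Flna and Ifit2 without CYM50358 replicate 3, where Clic5, Col4a5, Gpx4, Hsp90b1, Itgb1, Nid1, Thsd7a and Tpm4 were lost too. Without vehicle replicate 1, Gpx4 (0.072), Col4a5 (0.079), Lama1 (0.081), Ifit2 (0.092), Thsd7a (0.11) and Clic5 (0.14) were lost, without vehicle replicate 3 Itgb1 (0.051), Nid1 (0.066), Tpm4 (0.094) and Ifit2 (0.10), and without CYM50358 replicate 1 Itgb1 (0.058). Beside the list changes, reads from mitochondrial DNA made up 3.30% to 3.46% of each CYM50358 library and 2.60% to 3.18% of each vehicle library. Of 11 genes encoded there 11 stood higher (camera adjusted p = 0.0019, and adjusted p = 0.42 with an estimated correlation). So did 43 of 50 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.00024, and adjusted p = 0.59 with an estimated correlation), a call lost without CYM50358 replicate 3 (0.05). Of 43 genes of the cytosolic ribosome 37 stood higher (camera adjusted p = 0.0019, and adjusted p = 0.61 with an estimated correlation), a call lost without vehicle replicate 1 (0.43) or CYM50358 replicate 3 (0.25). Of these 3 lists, limma called 1 gene, of nuclear oxidative phosphorylation.

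Among the receptors, S1pr2 fell after CYM50358 (39.4 ± 1.94 to 29.0 ± 3.04, log2 fold change -0.43, adjusted p = 0.019), a call lost without vehicle replicate 1 (0.052) or 3 (0.067) or CYM50358 replicate 3 (0.069), and S1pr3 (15.0 ± 2.51 against 10.2 ± 0.40, adjusted p = 0.053) and S1pr1 (adjusted p = 0.83) did not pass. After ApoM the values were 32.1 ± 2.52 for S1pr2 (adjusted p = 0.47), 11.5 ± 1.73 for S1pr3 (adjusted p = 0.77) and 0.84 ± 0.54 for S1pr1 (adjusted p = 0.98). As a set, 10 of 12 genes of sphingosine-1-phosphate handling stood lower after ApoM (camera adjusted p = 0.0037, and adjusted p = 0.33 with an estimated correlation). That call was lost without vehicle replicate 3 (0.057). Col4a3 and Col4a4 did not pass in either treatment against vehicle, and Col4a5 did not after ApoM; without vehicle replicate 3, Col4a4 was lower after CYM50358 (adjusted p = 0.00033).

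The direct comparison of ApoM-treated with CYM50358-treated cells uses no vehicle library. Angptl4 was 57.1 ± 4.24 after ApoM and 9.78 ± 0.70 after CYM50358 (n = 3 each; log2 fold change 2.43, SE 0.10, adjusted p = 5e-13), and Aldh1l2 (1.15), Pdk4 (1.13), Kank3 (0.82) and Klf11 (0.68) were also higher after ApoM. Scd1 was lower after ApoM (86.8 ± 6.92 against 275.1 ± 51.9, -1.64, SE 0.10, adjusted p = 4.3e-10), as were Fdps (-1.23), the sterol synthesis gene Nsdhl (-1.04), Scd2 (-0.97) and Insig1 (-0.95). Of 26 cholesterol genes, 22 were lower after ApoM and none higher (25 and 0 adjusted over the list alone), with Cyp51 at -0.85, Msmo1 at -0.69 and Hmgcs1 at -0.80; camera's adjusted p was 1.2e-53, and the adjusted p = 0.081 with an estimated correlation. Lysosome genes were lower in 16 of 35 cases and higher in none (20 and 0 adjusted over the list alone; camera adjusted p = 1.3e-16). Genes of fatty acid synthesis were lower in 10 of 30 cases and higher in 1 (13 and 3 adjusted over the list alone; camera adjusted p = 4.3e-10). Stress response genes were higher after ApoM in 7 of 32 cases and lower in none (12 and 0 adjusted over the list alone; camera adjusted p = 2e-10), led by Psat1 (0.64), the amino acid transporter gene Slc7a5 (0.62), Asns (0.45) and Phgdh (0.34). The lysosome, fatty acid synthesis and stress response lists were the only calls that held with an estimated correlation in any of the 4 comparisons, each at adjusted p = 0.049. Against vehicle, lysosome genes stood higher after both treatments, with medians of 0.053 after ApoM and 0.284 after CYM50358. For ApoM camera's adjusted p was 0.00064, and the adjusted p = 0.33 with an estimated correlation.

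Fatty acid oxidation genes were higher after ApoM in 9 of 30 cases and lower in none (13 and 1 adjusted over the list alone), including Cpt1a (0.59) and Ucp2 (0.55); camera's adjusted p was 2.5e-07, and the adjusted p = 0.13 with an estimated correlation. Basement membrane genes were higher after ApoM in 7 of 25 cases and lower in none (11 and 0 adjusted over the list alone), and these included 3 chains of collagen IV and the perlecan gene: Col4a4 (283.6 ± 43.6 against 194.1 ± 5.34, 0.53), Col4a5 (1068 ± 109 against 849.1 ± 68.0, 0.33), what remained of Col4a3 (22.5 ± 0.79 against 15.6 ± 1.92, 0.51, adjusted p = 0.012) and Hspg2 (0.32). Camera's adjusted p for that list was 6.1e-08, and the adjusted p = 0.11 with an estimated correlation. Col4a3 was lost without ApoM replicate 1 (0.061) or 2 (0.081), and Col4a5 without ApoM replicate 1 (0.12) or CYM50358 replicate 2 (0.087). Against vehicle, the basement membrane list had a median of -0.018 after ApoM (camera adjusted p = 0.94) and of -0.149 after CYM50358. Spp1 was lower after ApoM than after CYM50358 (-0.78).

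Other lists moved beside these. Of 50 nuclear genes of oxidative phosphorylation 44 stood lower after ApoM (camera adjusted p = 8.6e-06, and adjusted p = 0.43 with an estimated correlation). Of 43 genes of the cytosolic ribosome 34 stood lower (camera adjusted p = 0.0086, and adjusted p = 0.71 with an estimated correlation), a call lost without ApoM replicate 1 (0.096) or 2 (0.24) or CYM50358 replicate 3 (0.64). Of 9 mesangial and fibroblast markers 8 stood higher (camera adjusted p = 0.087, fry adjusted p = 0.015, and 0.11 by fry with the block). Limma, edgeR and DESeq2 called 0 genes of these 3 lists, with 11, 4 and 1 at an unadjusted p under 0.05. Of 10 parietal and tubular markers 1 was higher and 2 were lower after ApoM (1 and 3 adjusted over the list alone), and camera passed the list without ApoM replicate 3 (0.045) or CYM50358 replicate 1 (0.033), against 0.087 with all libraries. Endothelial and leukocyte markers did not pass (camera adjusted p = 0.98 and 0.42, fry 0.87 and 0.44).

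In total 170 genes were higher and 190 lower after ApoM of 13878 tested, and same-numbered libraries of these groups deviated together, so the fit with replicate number as a block is set beside it: 671 higher and 503 lower, 1174 in all. With the block, camera also passed the fibrillar matrix list (adjusted p = 0.025 against 0.11) and the mitochondrial DNA list (0.033 against 0.11). Without the block these lists had adjusted p = 0.58 and adjusted p = 0.32 with an estimated correlation. The unblocked count was 126 without ApoM replicate 1, 143 without ApoM replicate 2 and 147 without CYM50358 replicate 2, and on the recovered reads edgeR called 214 and DESeq2 595. At an unadjusted p under 0.05 there were 2115 genes, and the groups did not overlap for 19.5% of genes against 10% by chance.

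**Figure D4:**
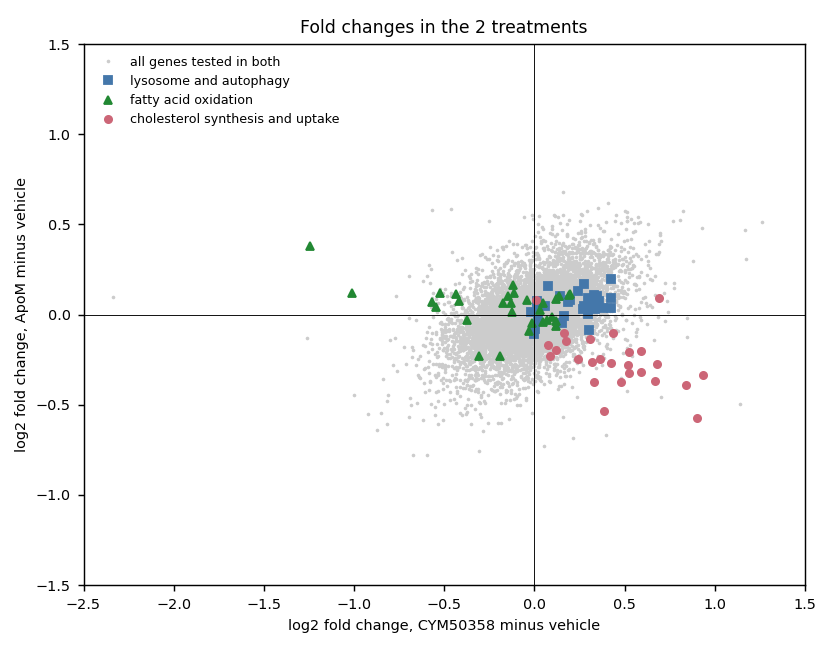
Log2 fold change after ApoM (vertical) against that after CYM50358 (horizontal), each minus the same 3 vehicle libraries, for 13658 genes tested in both; colours mark 3 gene lists. Cholesterol genes lie to the right and mostly below 0 (medians 0.43 and -0.25), lysosome genes to the right (median 0.28), and the lowest fatty acid oxidation genes to the left.

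Across the 13658 genes tested in both, the 2 sets of fold changes had a correlation of 0.444, with genes not being independent replicates. Unchanged groups simulated against the same 3 vehicle libraries gave a mean of 0.459 over 100 draws, from -0.735 to 0.902; the simulated libraries were drawn independently, without the pairing of same-numbered ApoM and CYM50358 libraries. The covariance was 0.0117 against a simulated mean of 0.0092 (-0.0108 to 0.0416). The 3 vehicle libraries are too few to be split, so part of any likeness can come from them. Mt1 was the gene called in both treatments that rose in both, where independent lists would share 0.027, and Scd1 fell after ApoM and rose after CYM50358, where independent lists would share 0.054. No gene fell in both. The numbers for independent lists leave out the shared vehicle libraries, so they are not what unchanged groups would give.

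Whether treated cells moved against the knockout difference was read from the genes called between the genotypes. After ApoM, 2876 of 5943 such genes (48.4%) had a fold change opposite in sign to the knockout difference, and after CYM50358 2762 of 5942 (46.5%). Simulated unchanged treatments gave 43.1% to 56.2% and 43.6% to 55.5% over 100 draws each. The correlations across these genes were -0.004 and 0.02, inside the simulated -0.12 to 0.12 and -0.12 to 0.13, and the covariances -0.0004 and 0.0034, inside -0.0146 to 0.0159 and -0.0168 to 0.0263. Of the 193 genes called both after CYM50358 and between the genotypes, 90 had opposite signs, and of the 5 for ApoM 2 had. No vehicle library is shared between these comparisons. The knockout difference thus rests on a set that is not the baseline of the treated cells, and 520 genes lay over 2-fold apart between the sets. The shares therefore cannot tell whether treated cells neared wild-type levels. Angptl4 was 11.5 ± 2.75 in wild-type cells, 53.4 ± 4.19 in the vehicle cells of the treatments and 9.78 ± 0.70 after CYM50358. Scd1 moved away, at 67.7 ± 9.20, 122.9 ± 9.07 and 275.1 ± 51.9.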

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

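The direct test between the treatments was planned for all genes, and Scd1 was picked for its calls in these data. The tests by thinning of reads and by the list median of the direct comparison were chosen after the results were seen.

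Scd1 went opposite ways in the 2 treatments, falling after ApoM (log2 fold change -0.50) and rising after CYM50358 (1.14), and the test between the treated groups gave -1.638 (adjusted p = 4.3e-10), with all 3 ApoM libraries below all 3 CYM50358 libraries. Scd1 was picked as the gene called in both treatments with opposite signs. The direct value is the gap between those 2 fold changes, so it is not separate support for them. Groups of 3 are too small for a search for outlying libraries.

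Genes of cholesterol synthesis and uptake were higher after CYM50358 by camera, a call that was lost at adjusted p = 0.18 with an estimated correlation. With reads thinned to equal totals the median of the list was 0.433, against 0.43 before. Signal is already scaled to depth and thinning leaves its expected value unchanged, so that test cannot decide about depth. A single library does not account for the shift, since the lowest median without each library in turn was 0.360. Vehicle libraries with low values stay open: ApoM-treated minus CYM50358-treated cells, which use none of them, gave a median of -0.696, but the list also stood lower after ApoM, and low vehicle values with a fall after ApoM would give the same number. An action of the drug on lipid metabolism stays open beside it, as a hypothesis, as do differences in solvent or handling; whether such an action runs through S1PR4, whose transcript had 0 reads in the vehicle cells, was not tested.

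The same list stood lower after ApoM, where limma and edgeR with all libraries called none of its 26 genes, DESeq2 called 1, 19 had an unadjusted p under 0.05 and 17 fell adjusted over the list alone; without vehicle replicate 1 limma called Fdps (adjusted p = 0.01) and Cyp51 (0.02). The highest median without each library in turn was -0.177, without vehicle replicate 3, so a single library does not account for the shift. Thinning to equal totals gave -0.249, which cannot decide about depth, for the reason given above. An action of ApoM was not tested apart from a vehicle group with high values, both stay open, and the list's call was lost (adjusted p = 0.33 with an estimated correlation).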

How the results depend on the processing

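The fits on recovered reads, the thinning of reads, camera with the block, the subtraction of chromosome medians and the single fit of all libraries were chosen after the data were seen; the others were planned. The cause of each change below was not tested. Of the counts of genes, that between the genotypes stayed within 1.5 times 6395 under all alternatives except the 2-fold minimum (871), and was 5025 to 6631 without each library and 7048 with the replicate block. For ApoM (6 genes) the count was 0 to 12 without each library, 0 without a filter, 0 with all libraries in one fit, 0 with the 2-fold minimum, 17 with the replicate block, 3 by edgeR with each of 3 scalings, 53 by edgeR without a filter, 11 by edgeR with the replicate block and 18 by DESeq2. For CYM50358 (359) it was 81 to 473 without each library, 1 without a filter, 9 with the 2-fold minimum, 958 by the authors' deposited table, 165, 164 and 174 by edgeR with TMM, DESeq2 and upper-quartile factors, 710 by edgeR without a filter, 716 by DESeq2 and 532 with the replicate block. For ApoM against CYM50358 (360) it was 126 to 536 without each library, 6 without a filter, 1174 with the replicate block, 197 with all libraries in one fit, 13 with the 2-fold minimum, 214, 216 and 229 by edgeR with the same scalings, 593 by edgeR without a filter, 834 by edgeR with the replicate block and 595 by DESeq2. ApoM and vehicle libraries, and CYM50358 and vehicle libraries, were not taken as paired. Their same-numbered correlations were 0.14, -0.12 and 0.09, and 0.09, -0.16 and -0.03, so not above 0.1 in each case. Between the genotypes and between the treatments the blocked limma and camera fits changed no other call on which the report rests. Of 29 lists, camera passed 3, 13, 17 and 13 in the order genotype, ApoM, CYM50358 and direct. With an estimated correlation 0, 0, 0 and 3 passed, with fry 4, 0, 7 and 10, and with fry and the replicate block 1, 0, 0 and 6. The share of genes opposite to the genotype difference was 52.1% for ApoM and 51.8% for CYM50358 among genes at least 2-fold apart. Among named genes that were called, taking each gene under each alternative, the call was lost in 12 cases and stayed in 2817 between the genotypes, in 37 and 95 for ApoM, in 202 and 1138 for CYM50358 and in 168 and 944 in the direct comparison, and none changed direction. Depth limits the lowest genes: 3 reads are a signal of 0.036 to 0.066.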

Other observations

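The GC content and window tests of chromosomes were set out before their results were seen, while the share of genes and all counts over splits of the libraries were chosen after.

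The vehicle knockout cells of the 2 tables, which the labels describe alike, stood apart. Their mean log2 values had a correlation of 0.98 across 14052 genes, and 520 genes lay over 2-fold apart, 158 higher and 362 lower in the treatment table. The tables were normalized separately, so these are levels without a test, and the genes were chosen after their values were seen. Mki67, a marker of dividing cells, was 4.47 ± 2.14 in the treatment table and 28.0 ± 2.19 beside the wild-type cells (55.6 ± 16.1), Col1a1 48.6 ± 10.8 and 472.9 ± 95.3, and the nuclear RNA Neat1 12.3 ± 4.39 and 94.7 ± 29.3 (SD, n = 3 each). In the other direction, Adh7 was 24.5 ± 4.92 and 0.44 ± 0.18, Pla2g7 30.5 ± 6.13 and 3.36 ± 0.34, and Xdh 27.5 ± 4.74 and 3.86 ± 0.13. Angptl4 was 53.4 ± 4.19 in the vehicle cells that CYM50358 lowered to 9.78 ± 0.70, and 14.4 ± 1.52 in the other vehicle knockout set and 11.5 ± 2.75 in wild-type cells. Nphs1, which encodes the podocyte protein nephrin, was low throughout, at 0.47 ± 0.01 in wild-type cells and below that in the mean of every knockout group.

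Genes of chromosomes 8 and 10 were shifted together between the genotypes. GC content and transcript length do not account for it, since with both trends removed the lower of the 2 medians was 0.265. At least 80.4% of the genes of each chromosome lay above the median of all genes. That share describes how broad the shift was, as a few strongly changed genes could not move a median in any case. Every 20 Mb window of both chromosomes with at least 20 tested genes had a positive median, the lowest 0.165, as a different number of copies of the whole chromosomes would give, and copy number differences between the lines, which would be separate from the loss of Col4a3, may therefore add to the list of called genes; DNA was not measured here. Levels across the tables gave medians of 0.33 and 0.30 for the first knockout set minus wild type on these chromosomes, but on chromosome 5 they gave 0.01 where the other set gave 0.17, and on chromosome 19 0.30 against 0.17. Near Col4a3, 40.5% of 121 genes within 10 Mb were called, against 37.8% of the genes of its chromosome 1 and 44.7% of all.

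With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Each other split mixes the real groups, so a large difference between them, of any origin, adds to the spread and leaves few calls. The counts therefore do not tell where a difference comes from. Between the genotypes the real split called 6395 genes and the highest other 0, and 1 of 10 splits gave as many. The numbers were taken to pair these libraries, and the other splits that part all 3 pairs also called 0. For CYM50358 the values were 359 and 7, with 1 split as large. For the direct comparison, where the numbers were also taken to pair the libraries, they were 360 and 0, with 1 split as large. The other splits there that part all 3 pairs called 0. For ApoM 3 of the 10 splits gave as many as the real 6, and the highest called 30 genes. Whether this comes from a structure of the samples was not tested.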
